A study of Mus musculus with 12 samples.

How the data were processed

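RNA sequencing was performed on primary hepatocytes, the main cell of the liver, from male mice in which both REV-ERB genes, Nr1d1 (REV-ERBα) and Nr1d2 (REV-ERBβ), carried loxP sites. Per the labels, the mice were 10 weeks old and had received, 2 weeks earlier, an AAV8 virus in which the hepatocyte-specific TBG promoter drove either Cre recombinase with GFP (KO) or GFP alone (control). No library holds Cre without loxP sites, so effects of Cre itself cannot be told apart from those of REV-ERB loss. Where loss of REV-ERB is spoken of below, it means the difference between KO-labelled and control cells. The cells were isolated with collagenase, plated on collagen and exposed for 8 h to the solvent DMSO or to 10 µM SR9009, a synthetic compound sold as a REV-ERB agonist. Polyadenylated RNA was selected, ribosomal RNA was depleted, and libraries were made with a NEBNext Ultra II kit, per the labels' protocols. The 12 libraries form 4 groups of 3, named control DMSO, control SR9009, KO-labelled DMSO and KO-labelled SR9009. The labels do not say whether the 3 replicates of a group are separate mice or separate plates of one preparation, so the p-values measure only the spread between these samples, which may be technical.

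Reads were processed with HISAT2 and StringTie on the mouse genome build mm9, per the submitters' processing notes. Versions, annotation release and strand setting are not given in the sources used here. The authors deposited one table of 37991 genes with a value per library. The file header does not name the unit. The deposited values were taken as FPKM because each library summed to a different total, 538521 to 604449, which excludes TPM, and because the low values of short genes fell on steps that scaled with gene length and differed between libraries. Coordinates are those of the deposited table. Because no strand setting is known, a gene and an overlapping gene on the opposite strand could not be separated, and members of near-identical families (Cyp2a, Cyp2b, Cyp2c, Cyp4a, Gstm, Mup) are uncertain, since reads can be split between copies. A genome of the mm9 build was not used here, and the annotation of another build served only to match 4 older symbols (Gm129 is Ciart, Sc4mol is Msmo1, Pkm2 is Pkm and Emr1 is Adgre1).

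Total read counts are not part of the table, but the size of the steps gives relative depth. Taking control DMSO library 1 as 100%, control SR9009 library 1 had 55.3%, KO-labelled DMSO library 1 63.4%, and the others 76.9% to 92.2%. For a gene of 1 kb, 1 step was 0.0185 FPKM in the deepest library and 0.0335 FPKM in the shallowest, so levels below about 0.1 FPKM rest on very few fragments. In no pair of libraries did more than 0.0535% of the tested genes hold equal values, so no library was entered under 2 names.

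Values were transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, which left 11213. A linear model with a mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (trend and robust variance), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method at a threshold of 0.05. Every adjusted p for a gene comes from this fit. A log2 fold change is on the log2(FPKM + 1) scale and understates the change of genes at low levels, and a fold is the ratio of the group means in FPKM. Errors after ± are SDs over n = 3 libraries. The comparisons were KO-labelled against control in DMSO, SR9009 against DMSO in each genotype, the difference between these SR9009 effects (the interaction), and KO-labelled against control under SR9009. Single levels of Nr1d1 and Nr1d2 were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

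Lists of genes (27 pathways and 6 cell types) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Where a list is called without further words, camera with the preset correlation called it. Of 40 such calls in the 3 main comparisons, 3 held with an estimated correlation. The fry test asks whether a list moves one way on balance, and does not compare it with other genes. The design, the alternatives, the lists and the rule for naming genes were set before the data were examined. The rule named Nr1d1 and Nr1d2, for each of the 3 main comparisons up to 8 genes per direction with the largest changes among those past the threshold, with separated groups and at least 5 FPKM in the higher one (passing over unnamed gene models), up to 10 interaction genes past the threshold, up to 4 members with the smallest p from each list spoken of, and any member of the clock list. A few genes that this rule names are not reported here.

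Before use, the fit was tested on simulated data for 11213 genes, some of which were given known changes. The changed genes were drawn only from those with a mean level above 5 FPKM, so the shares recovered do not cover genes at lower levels. For SR9009 in control it recovered 83.6% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 11 false calls. For the interaction it recovered 52.2%, 88.1% and 95.5% of the genes changed 1.5-fold, 2-fold and 4-fold, with 9 false calls. All these genes were changed at once, which eases the Benjamini-Hochberg threshold. In the real interaction 3 genes passed and the threshold was stricter, so these shares overstate what that test could find. Alternatives to each choice were also run: pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median-ratio rescaling, quantile normalization, a fit to the compared groups alone, limma without trend or robust variance, the replicate number as a block, and each library left out. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.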

Results

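Transcript levels were measured in 12 libraries of plated mouse hepatocytes, 3 for each combination of genotype (control or KO-labelled for both REV-ERBs) and treatment (DMSO or 10 µM SR9009 for 8 h). REV-ERBα and REV-ERBβ are nuclear receptors that repress transcription and form part of the circadian clock. The series title names effects of SR9009 that do not depend on REV-ERB, so the comparisons ask what changes when REV-ERB is deleted, what SR9009 changes in each genotype, and whether these SR9009 effects differ. Between 10611 and 10932 genes reached 1 FPKM in a library, and transcripts encoded in mitochondria made up 6.62% to 8.19% of the summed FPKM. Log2 values of 2 libraries of a group correlated across genes with r between 0.982 and 0.992, and those of 2 groups with r between 0.962 and 0.987.

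The levels of the targeted genes were examined first. Nr1d1 (REV-ERBα, ENSMUSG00000020889, mm9 chromosome 11, 98629246 to 98636647) stood at 18.5 ± 0.412 FPKM in control DMSO and 17.7 ± 0.459 in KO-labelled DMSO (exact permutation p = 0.1, two-sided; adjusted p = 0.492). Nr1d2 (REV-ERBβ, ENSMUSG00000021775, chromosome 14, 19036568 to 19071641) stood at 15.3 ± 1.87 and 16.2 ± 0.0949 FPKM (exact permutation p = 0.4; adjusted p = 0.633). The 3 KO-labelled values of Nr1d1 all lay below the control ones, with a mean lower by 4.34%, and Nr1d2 was not lower. The deleted part of each gene is not given in the sources used here, and the deposited values cover whole gene models, so these levels check neither the deletion nor the labels. With SR9009, Nr1d1 was at 19.5 ± 0.565 FPKM in control. In KO-labelled cells SR9009 raised Nr1d1 from 17.7 ± 0.459 to 22.1 ± 0.49 FPKM (log2 change 0.30, adjusted p = 0.00472). Between the genotypes under SR9009, the log2 difference of Nr1d1 was 0.17 (adjusted p = 0.0429). Its model overlaps that of Thra on the opposite strand by 1075 bp.

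**Figure D1:**
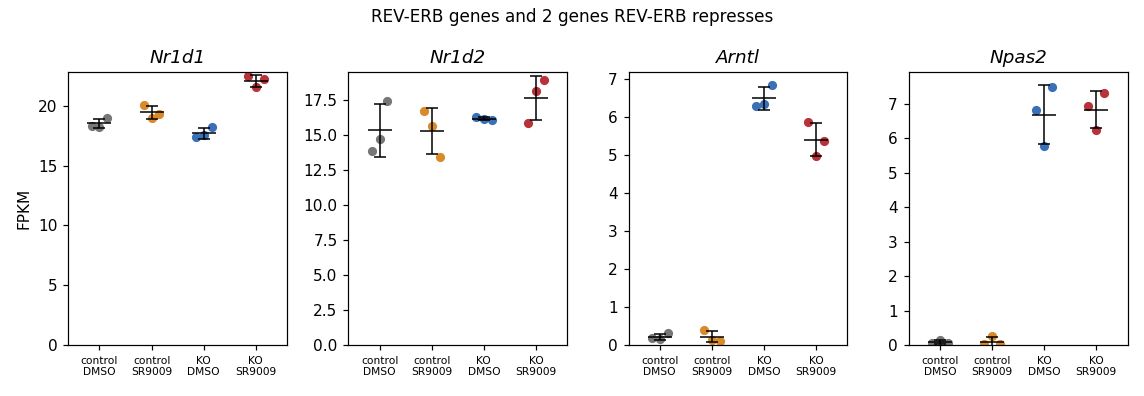
Levels in FPKM of Nr1d1, Nr1d2, Arntl and Npas2 in each of the 12 libraries (points) by genotype and treatment, with the mean and SD of each group of 3 (bars). The group means of Nr1d1 and Nr1d2 lie between 15.3 and 22.1 FPKM, while Arntl and Npas2 lie below 0.5 FPKM in control libraries and above 4.5 FPKM in KO-labelled ones.

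In DMSO, the genes that differed most between KO-labelled and control cells included a pair of clock regulators, a steroid dehydrogenase and enzymes of drug metabolism. Arntl (BMAL1) and Npas2, transcription factors that drive the clock and are repressed by REV-ERB, rose from 0.214 ± 0.0796 to 6.49 ± 0.307 FPKM (adjusted p = 1.04e-08) and from 0.0867 ± 0.048 to 6.68 ± 0.86 FPKM. The largest rise on the log2 scale was that of Lcn13, a secreted lipocalin, from 0.61 ± 0.299 to 34.9 ± 3.84 FPKM (log2 change 4.49, adjusted p = 2.63e-09). Loxl4, a lysyl oxidase that crosslinks collagen, rose 24.8-fold to 18.5 ± 1.78 FPKM. Hsd17b6, a steroid dehydrogenase, rose 8.59-fold from 31.2 ± 0.706 to 268 ± 15.4 FPKM. Among detoxifying enzymes, the glutathione transferase Gstm3 rose 7.25-fold to 751 ± 14.9 FPKM, the cytochrome P450 Cyp2a5 rose 6.66-fold to 2272 ± 25 FPKM, and its close relative Cyp2a4 rose from 0.751 ± 0.287 to 11.6 ± 1.53 FPKM. The 23 genes of the xenobiotic response moved both ways: 9 rose and 6 fell (10 and 7 adjusted over the list alone; adjusted p = 0.383, not called), with Cyp2b10 falling from 317 ± 28.6 to 98.4 ± 5.54 FPKM.

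Other genes fell in the KO-labelled cells. Cyp4a14, which hydroxylates fatty acids and is a target of PPARα, fell from 126 ± 3.3 to 13.5 ± 0.155 FPKM (log2 change -3.13, adjusted p = 2.16e-12). Slc13a5, the citrate importer of the plasma membrane, fell from 30.2 ± 2.82 to 3.44 ± 1.02 FPKM. Pltp, which transfers phospholipids between lipoproteins, Dio1, the deiodinase that activates thyroid hormone, and Tpm2, a tropomyosin, all fell, to 2.26 ± 0.129, 2.52 ± 0.228 and 1.02 ± 0.349 FPKM from 16.8 ± 1.84, 17.5 ± 1.48 and 9.36 ± 0.192 FPKM. The model of Pltp overlaps that of Ctsa, which has a higher mean level, by 1515 bp on the opposite strand. Ctgf, a matricellular protein induced by YAP, fell 4.7-fold from 125 ± 7.18 to 26.7 ± 7.66 FPKM, and the major urinary protein gene Mup17 fell from 1282 ± 154 to 258 ± 21.2 FPKM. In all, 2240 of 11213 genes passed the threshold (1307 higher and 933 lower), and 3642 had an unadjusted p under 0.05. The groups did not overlap for 41.2% of genes, where chance gives 10%.

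Of 14 genes listed as repressed by REV-ERB, 10 rose, 2 fell and 2 did not pass (10 and 2 adjusted over the list alone), with a median log2 change of 0.76 (adjusted p = 1.41e-05). The list call was lost when the correlation between genes was estimated (adjusted p = 0.0717 with an estimated correlation). Besides Arntl and Npas2, Insig2, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose from 74.2 ± 6.29 to 246 ± 17 FPKM, and G6pc, the last enzyme of glucose release, rose from 28.2 ± 2.24 to 78.9 ± 1.52 FPKM. Of 21 clock genes, 7 rose and 3 fell (the same numbers adjusted over the list alone), and the list was not called (adjusted p = 0.35), with a median of -0.05 against a mean of 0.31. Risers included Nfil3, a repressor of D-box genes (24.8 ± 1.54 to 47.3 ± 1.45 FPKM), Clock (2.53 ± 0.305 to 4.59 ± 0.106), Cry1 (9 ± 0.41 to 13.1 ± 0.425) and Dbp (1.69 ± 0.0694 to 4.42 ± 0.689). The model of Dbp overlaps that of Sphk2, which has a higher mean level, by 689 bp on the opposite strand. Per2, a repressor within the clock, fell from 8.19 ± 0.213 to 5.42 ± 0.311 FPKM.

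Metabolic lists moved in opposite directions in the KO-labelled cells. Of 23 cholesterol synthesis genes, 11 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 3.70e-08, adjusted p = 0.0717 with an estimated correlation). Among those that fell were Fdps, which makes farnesyl diphosphate (203 ± 6.11 to 112 ± 6.26 FPKM), and Idi1 (43.5 ± 0.589 to 24.8 ± 0.577). Of 16 glycolysis genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 3.70e-08, adjusted p = 0.0717 with an estimated correlation). Those that fell included the glucose transporters Slc2a2 (99.8 ± 6.31 to 45.3 ± 5.98 FPKM) and Slc2a1 (30.3 ± 3.28 to 16.1 ± 2.1). Of 9 gluconeogenesis genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.00211, adjusted p = 0.139 with an estimated correlation). Pyruvate carboxylase, Pcx, rose from 124 ± 3.52 to 179 ± 5.72 FPKM and the serine dehydratase Sds fell from 55.5 ± 2.38 to 29.9 ± 1.4. Of 17 fatty acid synthesis genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00534, adjusted p = 0.262 with an estimated correlation). The desaturase Scd1 was among them and fell from 872 ± 27.1 to 557 ± 3.66 FPKM. Of 22 genes of fatty acid oxidation and PPARα targets, 5 rose and 7 fell (6 and 9 adjusted over the list alone; adjusted p = 0.0291, adjusted p = 0.262 with an estimated correlation), and the list was no longer called after quantile normalization. Those that fell most were targets of PPARα: Cyp4a10 (103 ± 0.866 to 24.1 ± 2.57 FPKM), Acaa1b (583 ± 34.5 to 158 ± 1.02) and Vnn1 (20.5 ± 0.768 to 4.66 ± 0.444), besides Cyp4a14. Of 13 genes encoded in mitochondria, 8 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.00178, adjusted p = 0.392 with an estimated correlation). The cytochrome oxidase subunit mt-Co3 fell from 2211 ± 216 to 1447 ± 59 FPKM. The share of summed FPKM from all 37 genes of the mitochondrial chromosome, of which the list holds 13, did not fall with them. It was 6.62% to 8.18% in control DMSO and 7.23% to 7.34% in KO-labelled DMSO libraries. Of 10 markers of Kupffer cells, the macrophages of the liver, 4 fell and 1 rose in the same comparison (adjusted p = 0.173 for the list with an estimated correlation).

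Stress and early response genes also split. Of 19 endoplasmic reticulum chaperones, 12 rose and 0 fell (14 and 1 adjusted over the list alone; adjusted p = 5.53e-07, adjusted p = 0.11 with an estimated correlation). Those that rose included the disulfide isomerases Pdia4 (60 ± 2.17 to 100 ± 11 FPKM) and Pdia6 (115 ± 4.23 to 178 ± 5.55). Of 14 targets of p53, 8 rose and 1 fell (the same numbers adjusted over the list alone; adjusted p = 0.000976, adjusted p = 0.139 with an estimated correlation). Phlda3, which restrains AKT, rose from 2.47 ± 0.0886 to 12.6 ± 0.929 FPKM. Of 22 genes of the ATF4 response to amino acid and other stress, 12 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 2.13e-05, adjusted p = 0.204 with an estimated correlation). Atf3, a stress-induced transcription factor, fell from 68.8 ± 1.46 to 34.4 ± 0.87 FPKM. Of 13 immediate early genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 2.39e-07, adjusted p = 0.11 with an estimated correlation). Egr1, a transcription factor induced by growth signals, fell from 28.5 ± 2.18 to 11.6 ± 1.1 FPKM. Of 14 targets of YAP and SRF, 6 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.000308, adjusted p = 0.262 with an estimated correlation). Besides Ctgf, the keratin Krt18 fell, from 2710 ± 8.34 to 1773 ± 109 FPKM. The small heat shock protein Hspb1 fell from 179 ± 2.26 to 63.2 ± 4.12 FPKM, 1 of 3 heat shock genes of 14 that fell (3 adjusted over the list alone; adjusted p = 0.00434, adjusted p = 0.139 with an estimated correlation). Of 19 genes of MYC and ribosome biogenesis, 6 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.0125, adjusted p = 0.173 with an estimated correlation; not called after quantile normalization). Odc1, which makes polyamines, fell from 104 ± 1.14 to 77.2 ± 0.171 FPKM.

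Hepatocyte genes and markers of other cells moved too. Of 26 hepatocyte identity genes, 14 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 0.000477, adjusted p = 0.173 with an estimated correlation). The tryptophan dioxygenase Tdo2 rose from 176 ± 10.7 to 377 ± 21.2 FPKM and the transcription factor Foxa3 fell from 28.1 ± 2.38 to 16.5 ± 1.41. Of 10 Kupffer cell markers, 4 fell and 1 rose (the same numbers adjusted over the list alone; adjusted p = 0.0085, adjusted p = 0.173 with an estimated correlation). The scavenger receptor Marco fell from 9.52 ± 1.34 to 1.66 ± 0.462 FPKM. Of 6 endothelial markers, 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0223, adjusted p = 0.262 with an estimated correlation). Stab1, a scavenger receptor of sinusoidal endothelium, rose from 1.85 ± 0.304 to 4.16 ± 1.27 FPKM. Of 22 acute phase genes, 13 fell and 5 rose (14 and 5 adjusted over the list alone; adjusted p = 0.00172, adjusted p = 0.208 with an estimated correlation; not called after quantile normalization), although the largest change was a rise, that of serum amyloid P, Apcs, from 129 ± 4.5 to 319 ± 10.5 FPKM. Of 17 interferon response genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00136, adjusted p = 0.262 with an estimated correlation), and the faller, Isg15, had the smallest p (112 ± 1.33 to 38.6 ± 2.89 FPKM, adjusted p = 3.72e-07).

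**Figure D2:**
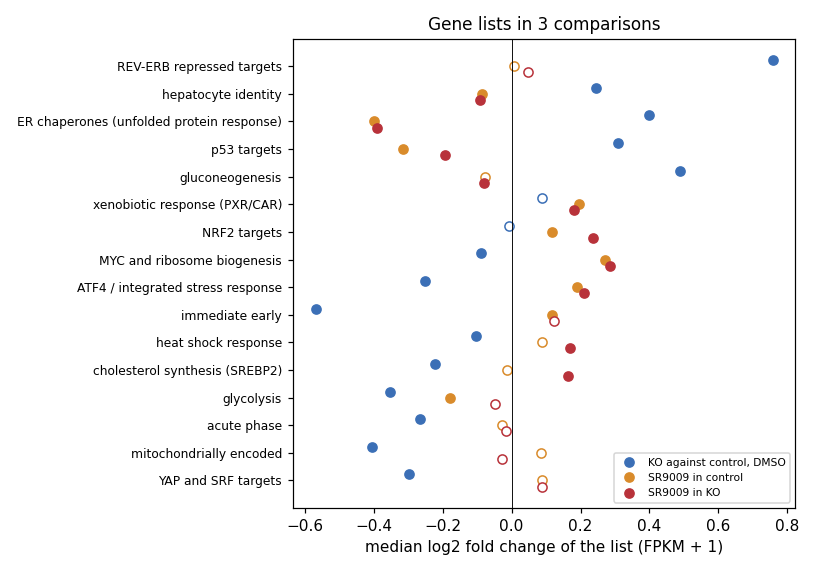
Median log2 fold change (FPKM + 1) of 16 gene lists for KO-labelled against control in DMSO, SR9009 in control and SR9009 in KO-labelled cells; filled points were called by camera with the preset correlation and open points were not. The REV-ERB list lies furthest right for the loss comparison (0.76) and near 0 for SR9009, while chaperones lie at 0.40 for loss and at -0.40 and -0.39 for SR9009.

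In control hepatocytes, SR9009 raised many genes of ribosome production and some genes of drug metabolism and oxidative stress, and lowered many chaperones. Of these lists, only ribosome production held (adjusted p = 0.0068 with an estimated correlation, against 0.168, 0.0897 and 0.0538 for the others in that order). Fam84a, a gene of little known function, rose from 0.241 ± 0.067 to 26.6 ± 5.98 FPKM (log2 change 4.46, SE 0.14, adjusted p = 4.99e-09). Cyp2b10, the cytochrome P450 induced by the xenobiotic receptor CAR, rose 3.42-fold from 317 ± 28.6 to 1084 ± 71.7 FPKM (adjusted p = 4.11e-08). Gadd45a, a stress gene that restrains growth, rose 3.69-fold from 112 ± 8.77 to 415 ± 7.94 FPKM (adjusted p = 4.11e-08). Vim, the intermediate filament vimentin, rose from 5.07 ± 0.667 to 20.9 ± 2.17 FPKM, Gstm3 from 104 ± 13 to 317 ± 15.8, the spindle orientation gene Insc from 3.55 ± 0.725 to 12.9 ± 2.71, and Osgin1, an oxidative stress gene, from 25.4 ± 7.33 to 78.9 ± 19.7. The pseudogene Cyp2c53-ps rose from 2.45 ± 1.35 to 15.8 ± 1.26 FPKM, but its model overlaps that of Cyp2c29 on the same strand.

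Genes that fell with SR9009 in control included Hpgd, which inactivates prostaglandins, from 71.7 ± 3.28 to 24.3 ± 1.33 FPKM (log2 change -1.52, adjusted p = 6.81e-07). Ppp1r3c, which directs glycogen synthesis, fell from 6.48 ± 0.316 to 1.75 ± 0.195 FPKM, and Rgs16, a regulator of G protein signals, fell from 80 ± 7.42 to 30.1 ± 3.29. Erbb3, a receptor of the EGF family, fell 2.42-fold, as did the ferritin receptor Scara5. BC025446 fell from 12.3 ± 0.92 to 5 ± 1.14 FPKM, and the biotinidase gene Btd, whose model overlaps that of Hacl1 on the opposite strand, fell from 16.3 ± 1.17 to 7.2 ± 1.99. Ppara, the receptor that drives fatty acid oxidation, fell from 36 ± 10.1 to 15.4 ± 7.1 FPKM (log2 change -1.22, adjusted p = 0.019), a call that ended without control DMSO library 3 (adjusted p = 0.0707), without control SR9009 library 1 or 3 (0.0665 and 0.0673) and in the fit to these groups alone (0.0833). In all, 924 genes passed (414 higher and 510 lower), 2426 had an unadjusted p under 0.05, and the groups did not overlap for 25.0% of genes against 10% by chance. The count depended on the control DMSO libraries: it was 536, 545 and 531 without library 1, 2 and 3, 605 without the 2 shallowest libraries and 376 when the fit used only these groups.

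Of 23 genes of the xenobiotic response, 11 rose and 0 fell with SR9009 in control (13 and 0 adjusted over the list alone; adjusted p = 2.11e-09, adjusted p = 0.168 with an estimated correlation). Among them were Por, which supplies electrons to cytochromes P450 (435 ± 13.3 to 649 ± 24.6 FPKM), and the drug exporter Abcb1a (4.8 ± 0.436 to 10.6 ± 0.912). Of 18 targets of NRF2, the regulator of antioxidant genes, 6 rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 0.000258, adjusted p = 0.0897 with an estimated correlation). The glutathione transferase Gsta1 rose from 327 ± 31.3 to 513 ± 57.4 FPKM. Of 19 genes of MYC and ribosome biogenesis, 12 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 8.66e-14), and this call held (adjusted p = 0.0068 with an estimated correlation). Myc rose from 90.7 ± 4.26 to 138 ± 10.6 FPKM and nucleolin, Ncl, from 78.1 ± 0.175 to 99.5 ± 1.51. Of 19 chaperones of the endoplasmic reticulum, 12 fell and 0 rose (15 and 0 adjusted over the list alone; adjusted p = 1.93e-12, adjusted p = 0.0538 with an estimated correlation). Pdia4 fell from 60 ± 2.17 to 40 ± 1.09 FPKM and Hsp90b1 from 225 ± 8.67 to 158 ± 9.05. Of 14 targets of p53, 5 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00015, adjusted p = 0.126 with an estimated correlation). Sesn1, a sestrin that restrains mTORC1, fell from 49.3 ± 1.33 to 28.3 ± 1.7 FPKM and the cell cycle inhibitor Cdkn1a from 147 ± 6.84 to 115 ± 3.18.

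A further 5 lists were called. Of 22 genes of the ATF4 response, 6 rose and 2 fell (the same numbers adjusted over the list alone; adjusted p = 0.00123, adjusted p = 0.399 with an estimated correlation). The secreted stress factor Gdf15 rose from 249 ± 5.84 to 347 ± 23.3 FPKM and Fgf21 fell from 7.74 ± 1.35 to 3.72 ± 0.746. Of 13 immediate early genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.000693, adjusted p = 0.265 with an estimated correlation). Fosl1, a subunit of AP-1, rose from 33.6 ± 4.01 to 54.4 ± 4.66 FPKM. Of 26 hepatocyte identity genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 0.000258, adjusted p = 0.224 with an estimated correlation). Tdo2 fell from 176 ± 10.7 to 113 ± 3.25 FPKM. Of 16 glycolysis genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.00775, adjusted p = 0.286 with an estimated correlation). Of 22 genes of fatty acid oxidation, 3 fell and 1 rose (the same numbers adjusted over the list alone; adjusted p = 0.0471, adjusted p = 0.355 with an estimated correlation), a call that ended with median-ratio rescaling. Among 14 genes repressed by REV-ERB, 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.51). Arntl stood at 0.218 ± 0.15 FPKM and Npas2 at 0.102 ± 0.133 FPKM with SR9009, adjusted p = 0.998 and 0.97. Both genes were already near the floor in control DMSO, so a further fall could hardly have been seen for them. Of 21 clock genes, 1 rose and 4 fell (the same numbers adjusted over the list alone; adjusted p = 0.499, not called). Of 10 Kupffer markers, 0 passed by limma in either direction, and none of the 10 had an unadjusted p under 0.05.

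**Figure D3:**
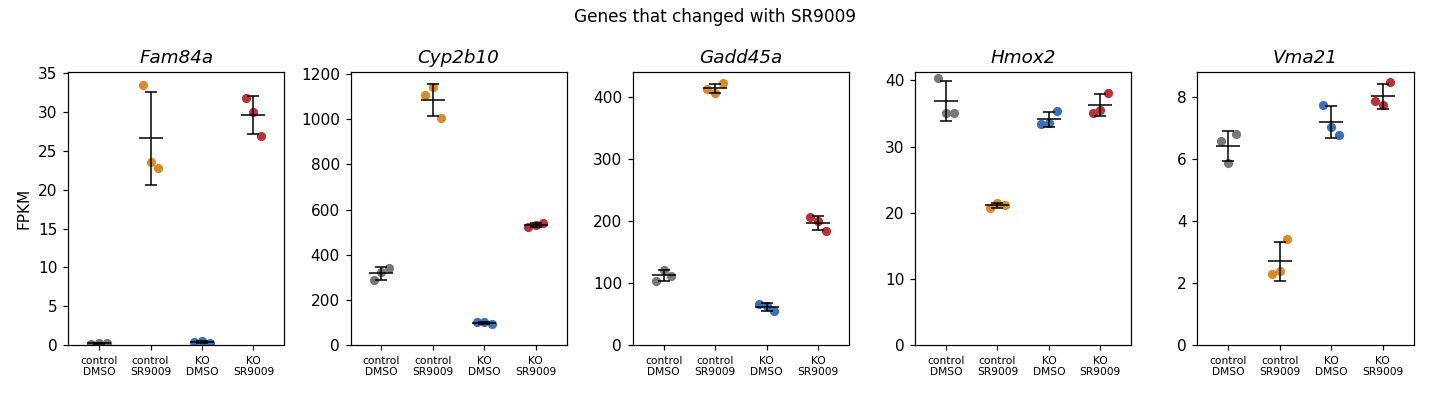
Levels in FPKM of 5 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (bars). Fam84a, Cyp2b10 and Gadd45a rise with SR9009 in both genotypes, whereas Hmox2 and Vma21 are lower with SR9009 in control libraries and at similar levels in the other 3 groups.

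In KO-labelled hepatocytes SR9009 changed many of the genes it changed in control. Fam84a rose from 0.407 ± 0.144 to 29.6 ± 2.43 FPKM (log2 change 4.44, SE 0.14, adjusted p = 2.58e-09) and Cyp2b10 rose 5.4-fold from 98.4 ± 5.54 to 531 ± 8.95 FPKM (adjusted p = 2.58e-09). Gadd45a rose from 61.8 ± 6.13 to 197 ± 11.2 FPKM, Insc from 5.43 ± 0.278 to 27.3 ± 3.79, Osgin1 from 35.5 ± 6.55 to 110 ± 38.7 and Cyp2c53-ps from 2.7 ± 0.172 to 16.2 ± 0.785. Slc13a5 rose 3.39-fold to 11.7 ± 1.12 FPKM, and Procr, the endothelial protein C receptor, rose from 2.6 ± 0.843 to 9.17 ± 1.68. Among genes that fell, Hpgd went from 55.6 ± 5.73 to 18.2 ± 1.5 FPKM (log2 change -1.56, adjusted p = 6.43e-07), Erbb3 from 30.6 ± 1.58 to 13 ± 2.42, Scara5 from 18.7 ± 0.97 to 7.84 ± 0.814, Rgs16 from 140 ± 8.36 to 62.7 ± 6.41, Cab39l from 117 ± 12.7 to 52.2 ± 6.44 and Pid1, which dampens insulin signals, from 17.6 ± 4.09 to 7 ± 0.396.

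The calls of Lpin1 and Ppara were less certain. Lpin1, a phosphatidate phosphatase, fell from 62.9 ± 19.7 to 20.4 ± 7.82 FPKM (log2 change -1.61, adjusted p = 0.0269), but Lpin1 did not pass without KO-labelled DMSO library 1 (adjusted p = 0.0868) or without KO-labelled SR9009 library 1 or 3 (0.0994 and 0.0608). Ppara fell from 27.7 ± 1.7 to 10.7 ± 2.39 FPKM (adjusted p = 0.0109; adjusted p = 0.0531 without KO-labelled SR9009 library 1). In all, 1107 genes passed (596 higher and 511 lower), 2564 had an unadjusted p under 0.05, and the groups did not overlap for 32.3% of genes against 10% by chance. The count was 703 without KO-labelled DMSO library 3, and 604 and 672 without KO-labelled SR9009 library 1 and 2.

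The lists called with SR9009 in KO-labelled cells began with NRF2 targets, of which 9 of 18 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 1.13e-09). This call held (adjusted p = 0.00987 with an estimated correlation), and heme oxygenase 1, Hmox1, rose from 53.2 ± 3.94 to 125 ± 11.8 FPKM, Gsta1 from 150 ± 12.2 to 277 ± 27.4 and thioredoxin reductase, Txnrd1, from 215 ± 10.2 to 307 ± 19.5. Of 19 genes of MYC and ribosome biogenesis, 11 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 3.91e-12), and this call held too (adjusted p = 0.00987 with an estimated correlation). Ncl rose from 70.1 ± 0.434 to 90.8 ± 3.22 FPKM. Of 23 xenobiotic genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 5.51e-10, adjusted p = 0.125 with an estimated correlation). Por rose from 285 ± 3.15 to 415 ± 14.2 FPKM. Of 19 chaperones, 11 fell and 0 rose (13 and 0 adjusted over the list alone; adjusted p = 8.43e-11, adjusted p = 0.0536 with an estimated correlation). Herpud1, which acts in the disposal of misfolded proteins, fell from 82.1 ± 12.4 to 37.8 ± 2.5 FPKM. Of 23 cholesterol synthesis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 2.05e-06, adjusted p = 0.118 with an estimated correlation). Idi1, an isomerase of the pathway, rose from 24.8 ± 0.577 to 32.4 ± 0.368 FPKM.

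Of 14 targets of p53, 4 fell and 0 rose with SR9009 in KO-labelled cells (7 and 0 adjusted over the list alone; adjusted p = 0.00041, adjusted p = 0.125 with an estimated correlation). Sesn1 fell from 62.7 ± 3.34 to 33.5 ± 2.8 FPKM. Of 26 hepatocyte identity genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 4.25e-05, adjusted p = 0.155 with an estimated correlation). The urea cycle enzyme Cps1 fell from 879 ± 13 to 523 ± 70 FPKM and Tat from 327 ± 38.2 to 175 ± 17.2. Of 22 genes of the ATF4 response, 7 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.00137, adjusted p = 0.443 with an estimated correlation). The pseudokinase Trib3 rose from 37.9 ± 1.41 to 54.4 ± 5.43 FPKM and Ddit4 fell from 16 ± 1.11 to 9.42 ± 0.952. Of 14 heat shock genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 0.00896, adjusted p = 0.155 with an estimated correlation). Hspa8, the constitutive HSC70, rose from 468 ± 10.7 to 586 ± 26.3 FPKM. Of 9 gluconeogenesis genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0298, adjusted p = 0.243 with an estimated correlation), the riser being G6pc (78.9 ± 1.52 to 176 ± 8.26 FPKM). Of 68 nuclear genes of oxidative phosphorylation, 2 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.0312, adjusted p = 0.888 with an estimated correlation), and the list was not called after median-ratio rescaling or quantile normalization. The 14 REV-ERB targets were not called (4 rose and 2 fell, also adjusted over the list alone; adjusted p = 0.596), with Arntl at 5.41 ± 0.437 FPKM and Npas2 at 6.82 ± 0.54 under SR9009. Of 21 clock genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.433, not called).

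Whether SR9009 acted differently in the genotypes was tested with the interaction. Hmox2, the constitutive heme oxygenase (ENSMUSG00000004070, chromosome 16, 4726361 to 4766742), fell from 36.8 ± 3.02 to 21.1 ± 0.399 FPKM in control and stood at 34.1 ± 1.1 and 36.3 ± 1.65 FPKM in KO-labelled cells (difference of log2 changes 0.86, SE 0.09, adjusted p = 0.00854). Vma21, an assembly factor of the proton pump that acidifies lysosomes, fell from 6.43 ± 0.498 to 2.71 ± 0.63 FPKM in control and stood at 7.2 ± 0.512 and 8.04 ± 0.408 FPKM in KO-labelled cells (difference 1.15, SE 0.16, adjusted p = 0.0414). Gstm3 rose 3.06-fold in control and 1.71-fold, to 1286 ± 19 FPKM, in KO-labelled cells, where it started higher (difference -0.83, SE 0.11, adjusted p = 0.0307). These 3 genes were the only ones that limma called, while 787 had an unadjusted p under 0.05. Without KO-labelled DMSO library 1 or 2, 0 genes passed, and without the 2 shallowest libraries Hmox2 had an adjusted p of 0.0926, Vma21 of 0.153 and Gstm3 of 0.164. The models of Hmox2 and 5730403B10Rik overlap by 16395 bp on opposite strands.

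Across the 11213 genes, the SR9009 effects in control and in KO-labelled cells, which share no library, correlated with Pearson's r = 0.57 and Spearman's rho = 0.509 (covariance 0.0372), although genes are not independent replicates. Of the 924 genes called in control, 882 (95.5%) changed in the same direction in KO-labelled cells by sign alone, and of the 1107 called in KO-labelled cells 1053 (95.1%) did so in control. Genes called up in both numbered 267, where independent lists of these sizes would share 22, and genes called down in both numbered 285, where 23.2 would be shared; 0 were called in opposite directions. Among these shared genes were Fam84a, Cyp2b10, Gadd45a, Hpgd, Erbb3 and Scara5. Genes called in control alone numbered 372 and in KO-labelled cells alone 555, but only 2 of these, Hmox2 and Vma21, passed the test of the difference itself. A gene that did not pass this test is not thereby shown to respond alike in the genotypes.

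**Figure D4:**
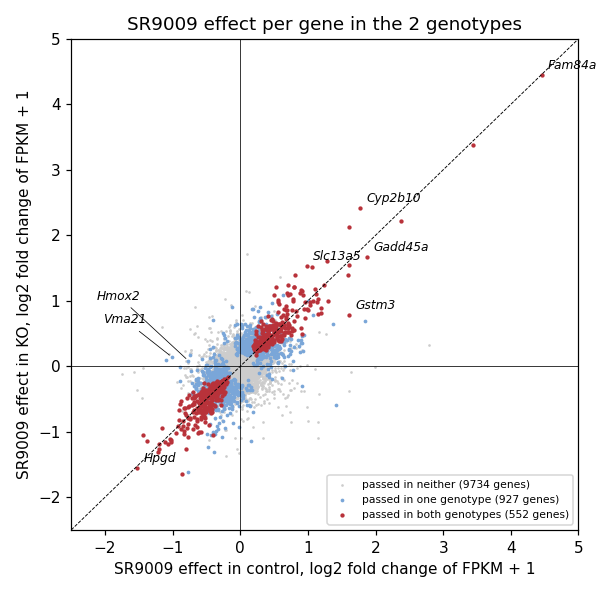
SR9009 effect of each of 11213 genes in control (horizontal axis) and KO-labelled cells (vertical axis), as log2 fold change of FPKM + 1, coloured by the number of genotypes in which it passed the threshold; the dashed line marks equal effects. The 552 genes that passed in both genotypes share their sign, and Hmox2 and Vma21 lie near 0 on the vertical axis.

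The genotype difference was also measured under SR9009. There, 2283 genes differed between KO-labelled and control cells (1450 higher and 833 lower; 3738 with an unadjusted p under 0.05), and 34.9% of genes had groups that did not overlap, against 10% by chance. Arntl stood at 0.218 ± 0.15 FPKM in control and 5.41 ± 0.437 in KO-labelled cells, Npas2 at 0.102 ± 0.133 and 6.82 ± 0.54, Hsd17b6 at 30 ± 1.15 and 279 ± 6.84, and Cyp4a14 at 113 ± 4.9 and 12.4 ± 0.671. The loss effects in DMSO and under SR9009, which share no library, correlated with r = 0.779 and rho = 0.668, and 2171 of the 2240 genes called in DMSO (96.9%) had the same sign. Genes up in both numbered 891 against 169.0 for independent lists, and genes down in both 593 against 69.3. Of 14 REV-ERB targets, 10 rose and 2 fell again (the same numbers adjusted over the list alone; adjusted p = 3.47e-05, adjusted p = 0.115 with an estimated correlation), while 1 of 10 Kupffer markers rose and 1 fell (also adjusted over the list alone; adjusted p = 0.0205, adjusted p = 0.203 with an estimated correlation). Of 4 lymphocyte and blood markers, 3 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.87, adjusted p = 0.00556, adjusted p = 0.203 with an estimated correlation). The count was 1518 when the fit used only these groups.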

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

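The test of the interaction by regrouping libraries was written before its result was seen, and the tests of library depth and of overlapping genes were chosen after seeing the result. SR9009 lowered Hmox2 and Vma21 in control cells alone, with differences between the genotypes of 0.86 and 1.15 log2 units. On the log2 scale it raised Gstm3 less in KO-labelled cells, with a difference of -0.83. In FPKM the rise of Gstm3 was larger in KO-labelled cells, so the direction of this difference depends on the scale. After the additive effects of genotype and treatment had been removed, libraries were exchanged at random between the genotypes within each treatment, and 1 of 100 groupings, the real one, gave 3 calls, while the highest other gave 2. This argues against a random grouping of these libraries as the source of the 3 calls together, but does not exclude it, and each of them ended under other settings.

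The fall of Hmox2 and Vma21 in control cells might come from library depth, since control SR9009 library 1 and KO-labelled DMSO library 1 were the shallowest. Leaving both out kept 0.965 of the Hmox2 difference and 0.977 of that of Vma21, so depth does not account for the size of the effects, although with fewer libraries the SEs grew and adjusted p was 0.0926 and 0.153. Reads of 5730403B10Rik, whose model overlaps that of Hmox2, could enter the Hmox2 value, but its own level changed with SR9009 in control by 0.013 (SE 0.337), an estimate too loose to decide the matter. Gstm3 may be nearer its ceiling in KO-labelled cells, where it starts 7.25-fold higher, although its gain in FPKM was larger there. Its reads may also be shared with Gstm6, which its model overlaps by 1417 bp. Vma21 was the least stable of the 3 (adjusted p = 0.0507 with a pseudocount of 0.1, 0.177 without a filter, 0.0738 with median-ratio rescaling, 0.0879 after quantile normalization and 0.0738 without trend and robust variance). Gstm3 ended without a filter (0.159), after quantile normalization (0.256) and without trend and robust variance (0.109).

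Camera also called 5 lists for the difference between the SR9009 effects. Of 23 cholesterol synthesis genes, 22 had a higher SR9009 effect in KO-labelled cells (median difference 0.14, adjusted p = 1.02e-06, adjusted p = 0.162 with an estimated correlation, fry adjusted p = 0.0444). Of 18 NRF2 targets, 14 did (median 0.15, adjusted p = 0.000943, adjusted p = 0.162 with an estimated correlation, fry adjusted p = 0.0426), and Hmox1 went from 98.6 ± 11.3 to 143 ± 17.6 FPKM in control and from 53.2 ± 3.94 to 125 ± 11.8 in KO-labelled cells. For glycolysis 14 of 16 were higher (adjusted p = 0.00633, adjusted p = 0.701 with an estimated correlation), for genes encoded in mitochondria 1 of 13 (adjusted p = 0.00633, adjusted p = 0.736 with an estimated correlation), and for YAP and SRF targets 3 of 14 (adjusted p = 0.0234, adjusted p = 0.736 with an estimated correlation). Cholesterol synthesis genes were lower in KO-labelled DMSO cells before SR9009 was added (11 of 23 fell), so a part of the difference can come from the shared DMSO libraries, and the cause was not tested. With limma, 0 members of these lists passed the interaction threshold over all genes, while 4 cholesterol synthesis genes and 3 NRF2 targets passed adjusted over the list alone, all higher in KO-labelled cells.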

How the results depend on the processing

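Leaving out the 2 shallowest libraries was chosen after seeing the data, and the other alternatives were set before. The number of genes called for SR9009 in control fell from 924 to 605 without the 2 shallowest libraries and to 376 when only the compared groups were fitted. With each library left out in turn it ranged from 531 to 920, and control DMSO libraries 1, 2 and 3 moved it most (536, 545 and 531). For SR9009 in KO-labelled cells, 1107 calls ranged from 604 to 1437, with 703 without KO-labelled DMSO library 3 and 604 and 672 without KO-labelled SR9009 libraries 1 and 2. For loss in DMSO, 2240 calls ranged from 1602 to 2712. Loss under SR9009 fell from 2283 to 1518 calls when only the compared groups were fitted. The balance of directions depended on these choices. For SR9009 in control, 414 genes higher and 510 lower became 479 and 441 without control SR9009 library 3. With median-ratio rescaling, 526 genes were higher and 596 lower with SR9009 in KO-labelled cells, and 1190 and 998 with loss under SR9009 (1171 and 999 after quantile normalization).

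The 3 interaction calls became 1 without a filter, 1 after quantile normalization, 1 without trend and robust variance, and 1 without the 2 shallowest libraries, where the call was a different gene. Leaving out a library gave 0 calls (KO-labelled DMSO library 1 or 2) to 5 (control DMSO library 1). Of 40 list calls, 3 held with an estimated correlation, and 38 lists were called with median-ratio rescaling and 38 after quantile normalization. The correlation of the SR9009 effects between genotypes, 0.57, ranged from 0.477 (pseudocount 0.1) to 0.644 (filter of 5 FPKM). Of 306 calls for named genes, 220 held under every alternative in which the gene was tested and 0 changed sign.

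The labels number replicates but do not pair them. Over 18 pairs of libraries with equal numbers, residuals correlated with r of -0.112 to 0.122, and 0 libraries matched best with their own number. With the replicate number as a block, calls were 2084 for loss, 793 and 958 for SR9009 in control and KO-labelled cells, 0 for the interaction (adjusted p = 0.0615 for Hmox2 and Gstm3 and 0.0828 for Vma21) and 2131 for loss under SR9009.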

Other observations

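The split tests were written before the results were seen, and the other tests in this part were chosen after seeing the result. Several genes outside the called lists moved far. In DMSO, the monocyte attractant Ccl2 was at 20.9 ± 8.94 FPKM in control and 77.5 ± 3.08 in KO-labelled cells (adjusted p = 0.000485), while its list of NF-kB targets and chemokines was not called (adjusted p = 0.763). The bile duct and progenitor factor Sox9 rose from 2.67 ± 0.532 to 9.09 ± 1.37 FPKM and osteopontin, Spp1, fell from 39.9 ± 0.863 to 24.4 ± 3.09, so markers of bile duct cells did not move as 1 group. Of 14 genes of bile acid synthesis and transport, 7 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0687), with the phospholipid exporter Abcb4 rising from 38.2 ± 1.22 to 75.3 ± 4.26 FPKM and Cyp7b1 from 57.5 ± 0.904 to 100 ± 5.43. Wipi1, which acts in autophagosome formation, fell with SR9009 from 15.8 ± 0.558 to 7.91 ± 0.579 FPKM in control and from 19.9 ± 0.656 to 10.9 ± 0.428 in KO-labelled cells. Acly, which makes acetyl-CoA for lipid synthesis, fell with SR9009 in control from 250 ± 6.39 to 172 ± 8.03 FPKM. Cyp2b10 carried opposite changes, falling from 317 ± 28.6 to 98.4 ± 5.54 FPKM with REV-ERB loss and rising with SR9009 in both genotypes.

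Whether the numbers of calls could come from any grouping of the libraries was asked by splitting each pair of groups in all 10 ways. For genes, 1 split, the real one, reached the count in each comparison: 2240 for loss in DMSO, 924 for SR9009 in control, 1107 for SR9009 in KO-labelled cells and 2283 for loss under SR9009, against at most 1 call in any other split. For lists, 1 split reached the 19 called for loss (highest other 18) and 1 reached the 10 called for SR9009 in control (highest other 8), while 3 splits reached the 11 called for SR9009 in KO-labelled cells (highest other 13). With 10 splits, no share under 0.05 can be reached. Each other split mixes the groups, so a part of the real difference remains in it and the rest widens the spread. Few gene calls can then be reached, and the splits do not rank gene calls against list calls. Among the list calls, those of MYC and ribosome genes (both genotypes) and NRF2 targets (KO-labelled cells), which held with an estimated correlation, are the firmest.

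SR9009 had similar effects in both genotypes, which is consistent with a route that does not need REV-ERB. The correlation of 0.57 was reached by 1 of 100 joint splits, the real one, and the highest other was 0.388, which argues against a random grouping. If effects were lost in KO-labelled cells and missed by the interaction test, signs would be near random there, but 95.5% of the genes called in control kept their sign (94.1% to 97.7% with each library left out). If a minority of cells that escaped deletion carried the response, effects in KO-labelled cells would be a fraction of those in control, but their median ratio was 1.06 over 1972 genes called for the average effect (0.96 to 1.14 with each library left out). Over the genes called in control, a choice that favours large effects there, it was 0.822, and the slope over all genes, which noise lowers, was 0.58, so the ratios argue against a small escaping share as the whole cause, although the share of deleted cells was not measured and the deletion rests on the labels and on the rise of Arntl and Npas2.

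The genotype difference in DMSO, called loss of REV-ERB here, and SR9009 in control moved 6 lists in opposite directions. These were chaperones, p53 targets, hepatocyte genes, the ATF4 response, immediate early genes, and MYC and ribosome genes. Such opposition might point to an agonist acting on REV-ERB. The lists of glycolysis and of fatty acid oxidation and PPARα targets, however, were called lower with both. Of all these calls, only that of MYC and ribosome genes with SR9009 held with an estimated correlation. An action through REV-ERB would be lost in KO-labelled cells, yet over the 113 members of the 6 lists the mean SR9009 effect there was 0.999 of that in control (0.888 to 1.13 with each library left out). It was lowest for immediate early genes, at 0.618 (0.486 to 0.87). The KO-labelled DMSO libraries helped to choose the 6 lists and also enter the SR9009 effect in KO-labelled cells. Chance deviations in them therefore push that effect toward the one in control, and the lists were not chosen anew with each library left out. The ratio thus cannot decide whether an action through REV-ERB was the cause, and it also relies on the labels of the KO-labelled cells. The MYC and ribosome genes rose with SR9009 in KO-labelled cells by a mean log2 change of 0.295, against -0.091 with loss. Camera with an estimated correlation called that rise (adjusted p = 0.00987). For these genes alone, it argues against a need for REV-ERB, if the labels hold. Of 14 genes listed as repressed by REV-ERB, 3 rose and 1 fell with SR9009 in control, and the list was not called. Over all genes, loss and SR9009 effects had a covariance of -0.000225 in control and -0.026 in KO-labelled cells. Unchanged groups were simulated, in which only the shared DMSO libraries link the effects. They gave 0.00845 to 0.0144 in control and -0.0143 to -0.0103 in KO-labelled cells. Both observed values lay below these ranges. With each library left out they were -0.00242 to 0.0061 and -0.0344 to -0.0245, but the ranges were simulated for 3 libraries per group and do not apply to those fits. The values over all libraries argue against sharing as the whole source of the opposition. Sharing can still be a part of it in KO-labelled cells, and the simulated genes were independent, which narrows the ranges.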
